A study of Mus musculus with 6 samples.

How the data were processed

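The samples are 6 mouse kidneys, 3 with a low and 3 with a high load of a mitochondrial tRNA mutation, each from a female of 100 weeks. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with an Illumina TruSeq RNA kit, and paired reads of 150 bp were sequenced on a DNBSEQ instrument. Whether the kit kept strand information is not given in the sources used here. The authors deposited a single table of raw counts per Ensembl gene with 1 column per kidney. The values are whole numbers and their sums differ between columns. The submitters' processing notes name fastp 0.23.2, HISAT2 2.2.1, SAMtools 1.11, featureCounts 2.0.1, edgeR without a version, and the genome build mm10. The annotation, the strand setting and the handling of reads that match several places are not given in the sources used here. Overlapping or antisense genes and near-identical copies therefore have uncertain counts, and 38 of the 167 genes covered by the naming rule have an exon that overlaps an exon of another gene.

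Groups and replicate numbers were taken from the sample titles, and mutation loads from the genotype labels. The labels give each library a mouse and a code of its own, and the 3 libraries of a group were treated as separate animals. Within groups, pairs of libraries differed by 21.4 to 100.02 times the variance of counting noise (chi-square per degree of freedom). For this reason no library was counted as a repeat of another. No sequencing batch is named in the labels. Total counts were 18729348, 17449270 and 18865997 in controls 1 to 3 and 18613697, 18498150 and 18090197 in high-load 1 to 3. Of 32285 gene IDs, 32158 matched a symbol in GENCODE M21, an annotation of mm10, which also gave the positions, overlaps, transcript lengths and GC contents.

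The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10, TMM scaling, a robust quasi-likelihood fit on group alone, a two-sided quasi-likelihood F test, and Benjamini-Hochberg adjustment over 15955 genes with a threshold of 0.05. TMM factors were 0.963, 0.944 and 0.974 in the controls and 1.139, 0.997 and 0.994 in the high-load libraries. Standard errors of log2 fold changes were derived from the F statistic. The biological coefficient of variation was 22.97%. An exact permutation test of a single gene in 3 against 3 animals cannot give a two-sided p below 0.1. For this reason only tests that share information across genes were used. Before the data were examined, 38 gene lists, the naming rule, the tests and most alternatives were fixed. Lists with at least 5 tested members (37 of 38) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. A list's own counts come from adjusting its members' p-values over the list alone. A list score is the mean over members of log2 CPM minus the mean of the controls.

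The naming rule took genes past the threshold with a mean of at least 1 CPM, groups that do not overlap and a symbol that is not a predicted model, up to 12 per direction by fold change, or the 5 with the smallest p where none passed. It also took the 4 members of each list with the smallest p, the 13 mitochondrially encoded protein genes as a group, and Fgf21, Gdf15, Ddit3, Trib3, Asns, Mthfd2, Havcr1 and Lcn2. Cth and Shmt2 were named after their values were seen, as the lower members of their list.

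The count tests were tested on simulated counts for 15955 genes with the real means, depths and dispersions, and 50 genes changed at each fold. For this comparison the quasi-likelihood test recovered 10% of genes changed 1.5-fold, 62% at 2-fold, 90% at 4-fold and 98% at 8-fold, with 10 false among 140 calls. DESeq2 1.42.0 recovered 26%, 80%, 90% and 100%, with 63 false among 211 calls, and limma-voom 4%, 48%, 88% and 98%, with 9 false among 128 calls. Simulated genes varied independently of each other, around edgeR's own estimate of each gene's dispersion. In the real data Trib3 (14.7-fold), Lcn2 (12.7-fold) and Gdf15 (7.86-fold) had edgeR adjusted p of 0.0772, 0.0981 and 0.0936. The shares recovered therefore do not tell how many real changes of these sizes the test would call. Camera found a simulated list of 30 genes shifted 1.5-fold among 15772 genes and called 0 of 50 unshifted lists. Lists whose members move together were not simulated.

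Alternatives were other scaling (DESeq2's size factors, library totals), leaving out mitochondrially encoded genes, other filters, DESeq2, limma-voom, a fit without robust estimation, the replicate number as a block, mutation load as a number, other thresholds, and leaving out each library in turn. Counts over the list alone with each library left out, camera with DESeq2's size factors, and DESeq2 on the genes of the edgeR test were added after seeing the data.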

Results

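RNA-seq of whole kidney was available from 6 female mice of 100 weeks that carried a mutation of TrnE, the mitochondrial gene for the glutamate tRNA. Mutation load is the percentage of mitochondrial DNA copies that carry the mutation. The control group held 3 kidneys with loads of 10%, 5% and 15%, and the high-load group held 3 kidneys with loads of 75%, 75% and 80%. They are called control 1 to 3 and high-load 1 to 3 here. Total counts per library ranged from 17449270 to 18865997, and 15955 of 32285 genes passed the filter on low counts. Values are CPM, counts scaled to library size with TMM factors, as mean ± SD with n = 3 per group, and fold changes are high load over control.

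The single comparison the design gives asks which kidney transcripts differ between a high and a low load of the mutation at the same age and sex. High-load kidneys had more mRNA of Atf5, a transcription factor of the integrated stress response, of S100a14, a small calcium-binding protein, and of Kcnk3, a two-pore potassium channel. These 3 genes rose at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 0 genes fell. Gene groups showed a wider picture. Mean scores of the stress response, tubule injury, interferon response and macrophage lists were higher in all 3 high-load libraries than in all 3 controls. Scores of fatty acid oxidation and of the proximal tubule were lower in all 3. At an unadjusted p under 0.05 there were 2233 higher and 1628 lower genes, and at an adjusted p under 0.1 there were 414 and 97. DESeq2 with its own filtering (23811 genes with a p) called 1074 and 624, and on the genes of the edgeR test it called 1069 and 642. Limma-voom called 0 of 15955.

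Atf5 (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658, minus strand, mm10) stood at 13.3 ± 1.83 CPM in controls and 80.1 ± 15.0 CPM in high-load kidneys, a log2 fold change of 2.59 with SE 0.17 and an adjusted p of 0.0218. S100a14 (ENSMUSG00000042306, chromosome 3, 90526856 to 90528837, plus strand) went from 0.965 ± 0.180 to 73.1 ± 31.2 CPM, a log2 fold change of 6.23 with SE 0.43 and an adjusted p of 0.0218. Kcnk3 (ENSMUSG00000049265, chromosome 5, 30588170 to 30625271, plus strand) went from 0.960 ± 0.147 to 9.33 ± 2.32 CPM, a log2 fold change of 3.27 with SE 0.27 and an adjusted p of 0.0398. Each was higher in 3 of 3 high-load libraries than in every control. Exons of Atf5 overlap those of Il4i1 and Nup62, and exons of Kcnk3 those of Gm9899, on the opposite strand. Whether counting used strand is not given in the sources used here. Among lower genes that met the other parts of the naming rule, groups that do not overlap included, the 5 with the smallest p failed the adjusted test. They were Kcnk5, another two-pore potassium channel (111 ± 4.18 against 54.4 ± 6.97 CPM, adjusted p 0.0696), and Corin, a protease that activates natriuretic peptides (4.58 ± 0.944 against 0.618 ± 0.173 CPM, adjusted p 0.0696). The others were Prob1 (adjusted p 0.0772), Slc52a3, a riboflavin carrier (adjusted p 0.0936), and the nuclear receptor Esrrb (adjusted p 0.0936). Exons of Corin overlap those of Gm20647.

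With 1 library left out, log2 fold changes were 2.44 to 2.71 for Atf5, 5.89 to 6.52 for S100a14 and 3.05 to 3.40 for Kcnk3. The count of called genes changed when 1 library was left out, which leaves 2 in its group. It was 0 without control 1, control 2, control 3 or high-load 1, 807 without high-load 2 (544 higher and 263 lower), and 3 without high-load 3, where Atf5 and S100a14 stayed and Kcnk3 had an adjusted p of 0.101.

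**Figure D1:**
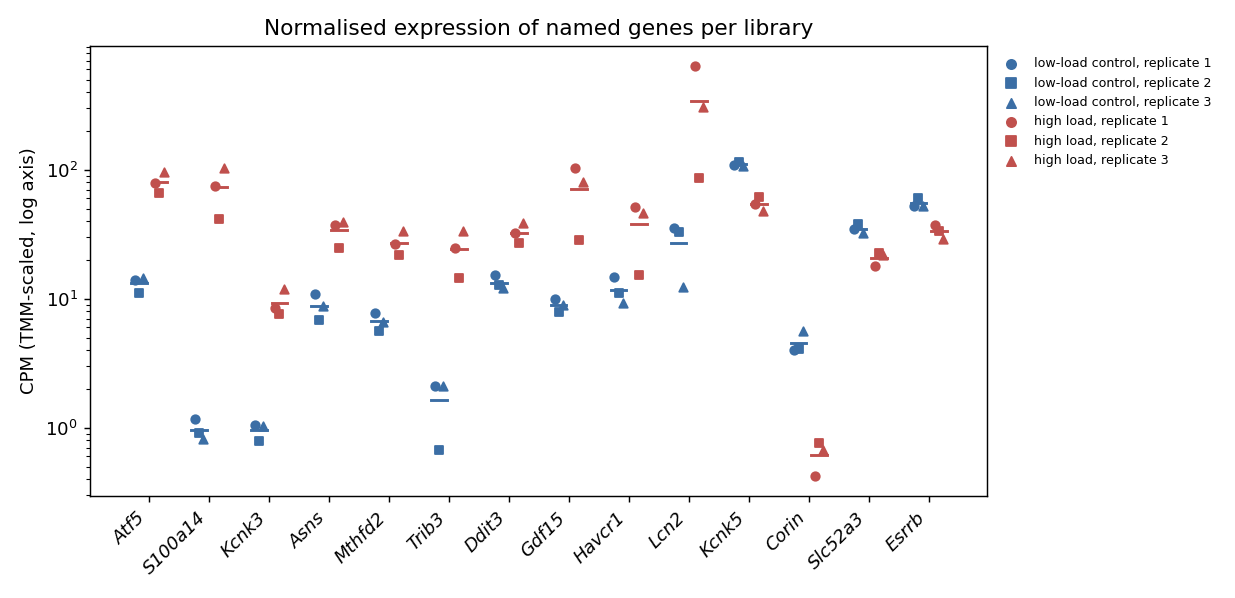
CPM per library on a log axis for 14 named genes, with controls in blue, high-load kidneys in red, a symbol per replicate and a bar at each group mean. Atf5, S100a14 and Kcnk3 passed the adjusted test, and Kcnk5, Corin, Slc52a3 and Esrrb did not. For the latter all 3 high-load values lie below all 3 controls, which the naming rule required.

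Genes of the mitochondrial integrated stress response, the programme that ATF4, ATF5 and CHOP drive when mitochondria or protein synthesis fail, rose as a list. The median log2 fold change of its 37 tested members was 0.95 (camera adjusted p 2.09e-23, and adjusted p = 0.392 with an estimated correlation). For it fry, which asks whether the members move one way, gave an adjusted p of 0.0446. Only Atf5 passed over all genes tested, and 23 members were higher and 2 lower when adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme, was at 6.71 ± 1.09 in controls and 27.2 ± 5.86 CPM in high-load kidneys (log2 fold change 2.02, SE 0.20). Asns, asparagine synthetase, was at 8.82 ± 2.00 and 34.0 ± 7.99 CPM (1.95, SE 0.24), and Aldh18a1, an enzyme of proline synthesis, at 7.50 ± 1.24 and 26.6 ± 5.97 CPM (1.83, SE 0.21). Adjusted p over all genes was 0.0696, 0.0772 and 0.0735 for these 3. Trib3, a pseudokinase induced by ATF4 and CHOP, was at 1.63 ± 0.836 and 24.3 ± 9.68 CPM (adjusted p 0.0772). Ddit3, which encodes CHOP, was at 13.4 ± 1.63 and 32.6 ± 5.73 CPM (adjusted p 0.0772), with exons that overlap Mars and Gm4189. Gdf15, a secreted stress hormone, was at 8.94 ± 1.04 and 70.4 ± 37.9 CPM (adjusted p 0.0936). The 2 lower members were Cth, which makes cysteine from cystathionine (275 ± 33.7 against 156 ± 51.7 CPM), and Shmt2, a mitochondrial serine and glycine enzyme (174 ± 40.2 against 109 ± 26.1 CPM). Their number was 1 without control 2, control 3 or high-load 1, and 0 without high-load 3. Fgf21, the other stress hormone of the list, had 7 counts over the 6 libraries and was not tested.

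Transcripts for burning fatty acids were lower in high-load kidneys. All 35 tested genes of fatty acid oxidation had a fold change below 1, with a median log2 fold change of -0.64 (camera adjusted p 1.83e-16, and adjusted p = 0.392 with an estimated correlation). None passed over all genes tested, and 23 were lower when adjusted over the list alone. Ppara, the nuclear receptor that switches on this pathway, was at 33.8 ± 9.98 CPM in controls and 13.95 ± 3.33 CPM in high-load kidneys (log2 fold change -1.28, SE 0.26). Acsl1, which activates long-chain fatty acids, was at 582 ± 54.8 and 317 ± 64.4 CPM, and the thioesterase Acot1 at 120.1 ± 30.1 and 56.2 ± 5.66 CPM. The first enzyme of long-chain oxidation, Acadvl, was at 149 ± 15.1 and 99.8 ± 8.82 CPM. The count of 23 was 11 without control 1, 8 without control 2 and 0 without high-load 3.

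Genes of the TCA cycle and of gluconeogenesis and ammonia production, both main tasks of proximal tubule mitochondria, were also lower as lists. The TCA cycle median over 21 genes was -0.40 (camera adjusted p 7.10e-06, and adjusted p = 0.551 with an estimated correlation), and 0 members passed over all genes and 0 adjusted over the list alone, or 3 without high-load 2. Without high-load 1 the median was -0.24. Pyruvate carboxylase, Pcx, was at 510 ± 125 and 238 ± 87.3 CPM, Pdha1 at 322 ± 31.7 and 229 ± 33.3 CPM, Dld at 345 ± 25.9 and 245 ± 41.5 CPM, and Mpc1 at 62.8 ± 4.28 and 48.2 ± 7.36 CPM. The gluconeogenesis and ammonia median over 9 genes was -0.94 (camera adjusted p 1.08e-05, and adjusted p = 0.392 with an estimated correlation), with 0 members past the threshold over all genes and 3 lower when adjusted over the list alone. They were the glutamate carrier Slc1a1 (275 ± 15.0 and 144 ± 37.2 CPM), the glutamine carrier Slc38a3 (239.9 ± 112 and 95.5 ± 24.2 CPM) and glutamate dehydrogenase, Glud1 (644 ± 109 and 428 ± 55.9 CPM). That count was 6 without high-load 1, 8 without high-load 2 and 0 without high-load 3.

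Proximal tubule markers moved with these groups. All 26 were below a fold change of 1, with a median log2 fold change of -0.87 (camera adjusted p 6.16e-09, and adjusted p = 0.392 with an estimated correlation). None passed over all genes or when adjusted over the list alone, where 11 passed without high-load 2. The median was -0.57 without high-load 1 and -1.27 without high-load 2. Mean log2 scores of the list against the control mean were -2.09, -0.37 and -0.81 in high-load 1, 2 and 3. The water channel Aqp1 was at 1250 ± 352 and 622 ± 116 CPM, the cystine carrier Slc3a1 at 549 ± 95.8 and 292 ± 99.4 CPM, the fatty acid transporter Slc27a2 at 4127 ± 317 and 2021 ± 866 CPM, and Cyp4b1 at 714 ± 550 and 213 ± 73.8 CPM, with a control mean of 397 CPM without control 2.

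Nuclear genes for mitochondrial machinery were lower by small amounts. Median log2 fold changes were -0.18 for 36 complex I subunits (camera adjusted p 0.000764, and adjusted p = 0.660 with an estimated correlation) and -0.19 for 41 subunits of complexes II to V (camera adjusted p 0.000338, and adjusted p = 0.660 with an estimated correlation). They were -0.23 for 20 mitochondrial chaperones and proteases (camera adjusted p 0.000873, and adjusted p = 0.551 with an estimated correlation) and -0.16 for 37 genes of mitochondrial tRNA charging and translation (camera adjusted p 0.00279, and adjusted p = 0.552 with an estimated correlation). The last medians were -0.19 for 24 genes of mtDNA replication and transcription (camera adjusted p 0.0162, and adjusted p = 0.552 with an estimated correlation) and -0.09 for 78 proteins of the mitochondrial ribosome (camera adjusted p 0.0190, and adjusted p = 0.723 with an estimated correlation). In these 6 lists 0 members passed over all genes and 0 when adjusted over the list alone. Ndufs1 of complex I was at 226 ± 6.16 and 159 ± 37.3 CPM, Uqcrc2 of complex III at 439 ± 6.85 and 305 ± 59.4 CPM. The protease subunit Clpx was at 131 ± 30.1 and 78.0 ± 6.43 CPM, and the mtDNA packaging factor Tfam at 48.4 ± 4.03 and 38.7 ± 3.09 CPM. Gars, which charges glycine tRNA in cytosol and mitochondria, was at 73.3 ± 4.09 and 94.8 ± 4.98 CPM. Without high-load 1 the medians were -0.053 for complex I, -0.027 for complexes II to V, -0.14 for chaperones and proteases, -0.089 for tRNA charging and translation and -0.024 for the ribosome. The complex I median was -0.28 without high-load 2. Without high-load 3 the medians were -0.25 for tRNA charging and translation and -0.13 for the ribosome, and without control 2 they were -0.12 for mtDNA replication and transcription and -0.053 for the ribosome. Without high-load 1 the camera adjusted p was 0.212 for complex I, 0.118 for complexes II to V, 0.359 for the ribosome and 0.0602 for mtDNA replication. Without control 2 it was 0.0868 for the ribosome and 0.0511 for mtDNA replication. With library totals alone the ribosome call was also lost, and without high-load 2, 1 gene of mtDNA replication and transcription was higher when adjusted over the list alone.

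The 13 protein genes of the mitochondrial genome did not pass as a list. Their median log2 fold change was 0.28 (camera adjusted p 0.255), 0 passed over all genes, and 1, mt-Co3, was higher when adjusted over the list alone (428 ± 36.3 against 820.3 ± 213 CPM), or 0 without any 1 of the controls or high-load 3 and 2 without high-load 1. Without high-load 1 the list was called higher (median 0.49, camera adjusted p 0.000298). The median was 0.17 without control 3 and 0.046 without high-load 3, where camera pointed down (adjusted p 0.833). mt-Co1 was at 38719.7 ± 4931 and 47013.6 ± 12361 CPM, and mt-Nd3 at 137 ± 178 and 40.7 ± 20.6 CPM, with a control mean of 34.5 CPM without control 1, below the high-load mean. These genes took 11.6%, 10.0% and 9.9% of counts in the controls and 10.4%, 11.7% and 15.9% in the high-load libraries. The 24 rRNA and tRNA genes of the mitochondrial genome, the mutated one included, were not analysed here.

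Markers of tubule injury rose as a list. Their median log2 fold change was 1.48 over 26 genes (camera adjusted p 9.99e-19, and adjusted p = 0.392 with an estimated correlation), with 0 past the threshold over all genes and 20 higher when adjusted over the list alone, or 13 without control 3. The chaperone clusterin, Clu, was at 474 ± 140 CPM in controls and 2462 ± 852 CPM in high-load kidneys. The repair factor Sox9 was at 3.58 ± 1.03 and 23.8 ± 11.5 CPM, S100a6 at 25.2 ± 6.13 and 85.3 ± 38.2 CPM, and the cell cycle inhibitor Cdkn1a at 27.7 ± 3.23 and 67.6 ± 12.4 CPM. Havcr1, the injury marker KIM-1, was at 11.7 ± 2.84 and 37.7 ± 19.6 CPM (adjusted p 0.120), and Lcn2, the injury marker NGAL, at 26.8 ± 12.5 and 340.4 ± 275 CPM (adjusted p 0.0981), with a high-load mean of 195 CPM without high-load 1.

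Lists of cell fate and early response genes were higher too, with 0 members past the threshold over all genes in each. Senescence and p53 genes had a median of 0.57 over 19 genes (camera adjusted p 1.56e-06, and adjusted p = 0.392 with an estimated correlation), with 8 higher when adjusted over the list alone, among them Cdkn2a (0.164 ± 0.163 and 2.32 ± 0.976 CPM, with a control mean of 0.0832 without control 3). Apoptosis and inflammasome genes had a median of 0.59 over 22 genes (camera adjusted p 0.000164, and adjusted p = 0.392 with an estimated correlation), with 6 higher when adjusted over the list alone, such as Casp4 (6.02 ± 0.985 and 16.3 ± 5.45 CPM) and Pycard. Cell cycle genes had a median of 0.90 over 29 genes (camera adjusted p 1.60e-11, and adjusted p = 0.392 with an estimated correlation), with 17 higher when adjusted over the list alone, such as Bub1b (2.31 ± 0.708 and 5.41 ± 0.0967 CPM) and Rrm2. That count was 0 without control 2, control 3 or high-load 3 and 11 without high-load 1. Immediate early genes had a median of 0.80 over 18 genes (camera adjusted p 5.89e-07, and adjusted p = 0.407 with an estimated correlation), with 7 higher when adjusted over the list alone, or 4 without control 2, control 3 or high-load 3. Among them Socs3 was at 11.4 ± 1.21 and 33.5 ± 12.7 CPM. The immediate early list was fixed as genes raised within minutes by handling or stress of the tissue. Whether handling differed between the groups was not tested. Extracellular matrix and fibrosis genes had a median of 0.57 over 30 genes (camera adjusted p 2.48e-07, and adjusted p = 0.407 with an estimated correlation), with 8 higher when adjusted over the list alone, such as the matrix protease Mmp14 (24.8 ± 2.96 and 52.0 ± 11.8 CPM) and fibronectin, Fn1. That count was 2 without control 1 or high-load 3, 5 without control 2, 1 without high-load 1, and 0 without control 3 or high-load 2. The median was 0.38 without high-load 2.

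Immune transcripts were higher in high-load kidneys. Interferon response genes had a median log2 fold change of 1.16 and all 32 tested lay above a fold change of 1 (camera adjusted p 2.09e-23, and adjusted p = 0.392 with an estimated correlation), with 0 past the threshold over all genes and 27 higher when adjusted over the list alone. The antiviral gene Isg15 was at 6.33 ± 0.347 and 18.0 ± 5.39 CPM, Bst2 at 19.1 ± 3.62 and 51.1 ± 14.3 CPM, and the nucleic acid sensor Zbp1 at 6.08 ± 1.34 and 16.2 ± 3.41 CPM. Macrophage and dendritic cell markers had a median of 0.98 over 24 genes (camera adjusted p 9.99e-19, and adjusted p = 0.392 with an estimated correlation), with 0 past the threshold over all genes and 22 higher when adjusted over the list alone, or 13 without control 2. The complement subunit C1qa was at 53.5 ± 3.54 and 139 ± 42.6 CPM, and the chemokine receptor Cx3cr1 at 16.0 ± 1.402 and 27.4 ± 1.81 CPM. B and plasma cell genes had a median of 1.80 over 22 genes (camera adjusted p 3.91e-06, and adjusted p = 0.392 with an estimated correlation), with 0 past the threshold over all genes and 6 higher when adjusted over the list alone, such as Igkc (663 ± 232 and 1872.5 ± 448 CPM). That count was 0 without any 1 of the controls and 18 without high-load 3, and the median was 0.59 without high-load 1. T and NK cell genes had a median of 0.99 over 23 genes (camera adjusted p 3.91e-06, and adjusted p = 0.551 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone, or 2 without control 1, 1 without control 2 and 5 without high-load 3. Thy1 was at 7.24 ± 3.25 and 18.7 ± 2.21 CPM. T and NK scores were 0.59, -0.67 and 0.08 in controls 1 to 3 and 1.43, 1.13 and 0.22 in high-load 1 to 3. Neutrophil markers, with 5 genes tested, had a median of 0.62 and were not called (camera adjusted p 0.128, 0 adjusted over the list alone). They were called higher without control 2 (median 1.495, 0.00493) or high-load 2 (median 1.12, 0.0235, with 1 gene passing over the list alone). The median was 0.22 without control 1, 0.25 without control 3 and 0.10 without high-load 3, and with 1 library left out 6 to 9 genes passed the filter and were tested.

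**Figure D2:**
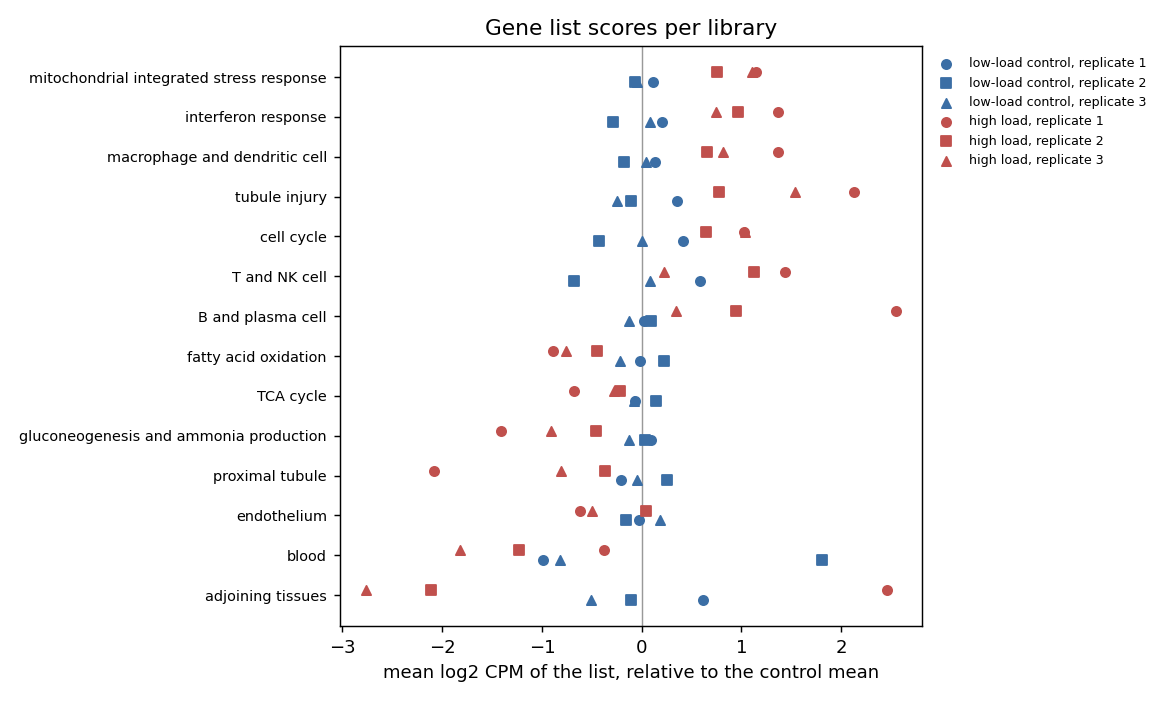
Mean log2 CPM of each gene list per library, relative to the mean of the 3 controls, with controls in blue and high-load kidneys in red. High-load 1 has the lowest proximal tubule score, -2.09, and the highest macrophage score, 1.37, and the adjoining tissue score is 2.46 in high-load 1 and -2.11 and -2.76 in high-load 2 and 3.

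Beside the immune and proximal tubule groups, high-load 1 stood apart from the other libraries on the first principal component (50.6% of the variance). Of the high-load libraries, high-load 2 lay nearest the controls on it (3.40, against 71.2 and 24.4 in high-load 1 and 3). Controls 1 to 3 lay at -22.0, -41.8 and -35.2. Markers of adjoining tissues (renal pelvis, fat and adrenal gland) gave scores of 2.46, -2.11 and -2.76 in high-load 1, 2 and 3. Of 16 listed genes 8 were scored, among them Krt5, Upk1a, Upk1b, Upk2 and Upk3a of the pelvis wall. Adipoq, Plin1 and Lep of fat and Cyp11a1, Cyp11b1, Cyp11b2, Cyp21a1 and Hsd3b1 of the adrenal gland were not. Cyp21a1 counts were 0, 0 and 0 in the controls and 18, 5 and 7 in high-load 1 to 3, and Cyp11b1 and Cyp11b2 had none. Uroplakin scores were 3.06, -3.52 and -3.86, so the list score says little about fat or adrenal gland. The list had a median log2 fold change of 1.30 and a mean of 1.20 over 8 genes where camera pointed down (adjusted p 0.668, 0 genes adjusted over the list alone). Macrophage scores in the same libraries were 1.37, 0.65 and 0.81, and B cell scores 2.55, 0.95 and 0.35. The adjoining tissue list was called lower without high-load 1 (median -3.27, 5.57e-09, 5 genes lower over the list alone) and higher without high-load 3 (median 2.15, 0.00393, 3 genes higher over the list alone). Camera also pointed up, without a call, when any 1 of the controls or high-load 2 was left out (0.668, 0.907, 0.738 and 0.946), and the median was 2.13 without control 1. Blood genes, mostly haemoglobins, had a median of -1.99 over 7 genes (camera adjusted p 0.0273, and adjusted p = 0.583 with an estimated correlation), with 0 adjusted over the list alone. The call was lost without control 2 (median -0.096, 0.506), high-load 2 (0.185) or high-load 3 (0.0936). Hba-a1 was at 321 ± 417 and 69.2 ± 46.3 CPM, with a control mean of 80.6 CPM without control 2 and a high-load mean of 44.2 CPM without high-load 1.

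Other nephron and cell type markers moved less. Thick ascending limb genes had a median of -0.42 over 11 genes (camera adjusted p 0.00887, and adjusted p = 0.392 with an estimated correlation). The salt cotransporter Slc12a1 was at 1460 ± 196 and 916 ± 129.7 CPM. Over the list alone 4 were lower, 2 without high-load 2 and 0 without any other 1 library, and the camera call was lost without control 2 (median -0.19, 0.0609). Endothelial markers had a median of -0.35 over 15 genes (camera adjusted p 0.000846, and adjusted p = 0.552 with an estimated correlation), with 0 adjusted over the list alone, or 10 without high-load 2. Their median was -0.15 without high-load 1 and -0.61 without high-load 2. Tek was at 52.9 ± 4.55 and 32.6 ± 6.85 CPM. Collecting duct genes were not called by camera (median 0.29 over 18 genes, adjusted p 0.101), except without control 2 (0.0358), but fry gave an adjusted p of 0.0122. Their median was 0.15 without control 2 and 0.13 without high-load 1. Over that list alone 5 were higher and 1 lower, and 1 higher and 0 lower without control 1, high-load 1 or high-load 3, and the lower gene did not pass without control 3. Among its members were the proton pump subunit Atp6v0d2 (32.1 ± 4.94 and 83.8 ± 11.5 CPM) and the intercalated cell factor Foxi1 (30.2 ± 8.22 and 53.9 ± 3.60 CPM). Distal tubule genes had a median of -0.34 over 8 genes (camera adjusted p 0.274), with the calcium channel Trpv5 alone past the list's own adjustment (18.6 ± 0.590 and 66.1 ± 23.7 CPM), joined by 1 lower gene without high-load 1, where the median was -0.19. Podocyte markers had a median of -0.18 over 12 genes (camera adjusted p 0.406), and fibroblast, pericyte and smooth muscle markers 0.22 over 15 genes (camera adjusted p 0.449), each with 0 adjusted over the list alone. The podocyte median was -0.11 without control 1, -0.34 without high-load 2 and 0.10 without high-load 1, where camera pointed up (adjusted p 0.518). The fibroblast, pericyte and smooth muscle median was 0.10 without control 2, 0.39 without control 3, 0.12 without high-load 1 and 0.40 without high-load 3, and camera pointed down without high-load 2 (adjusted p 0.900). None of these 6 lists had a member past the threshold over all genes.

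**Figure D3:**
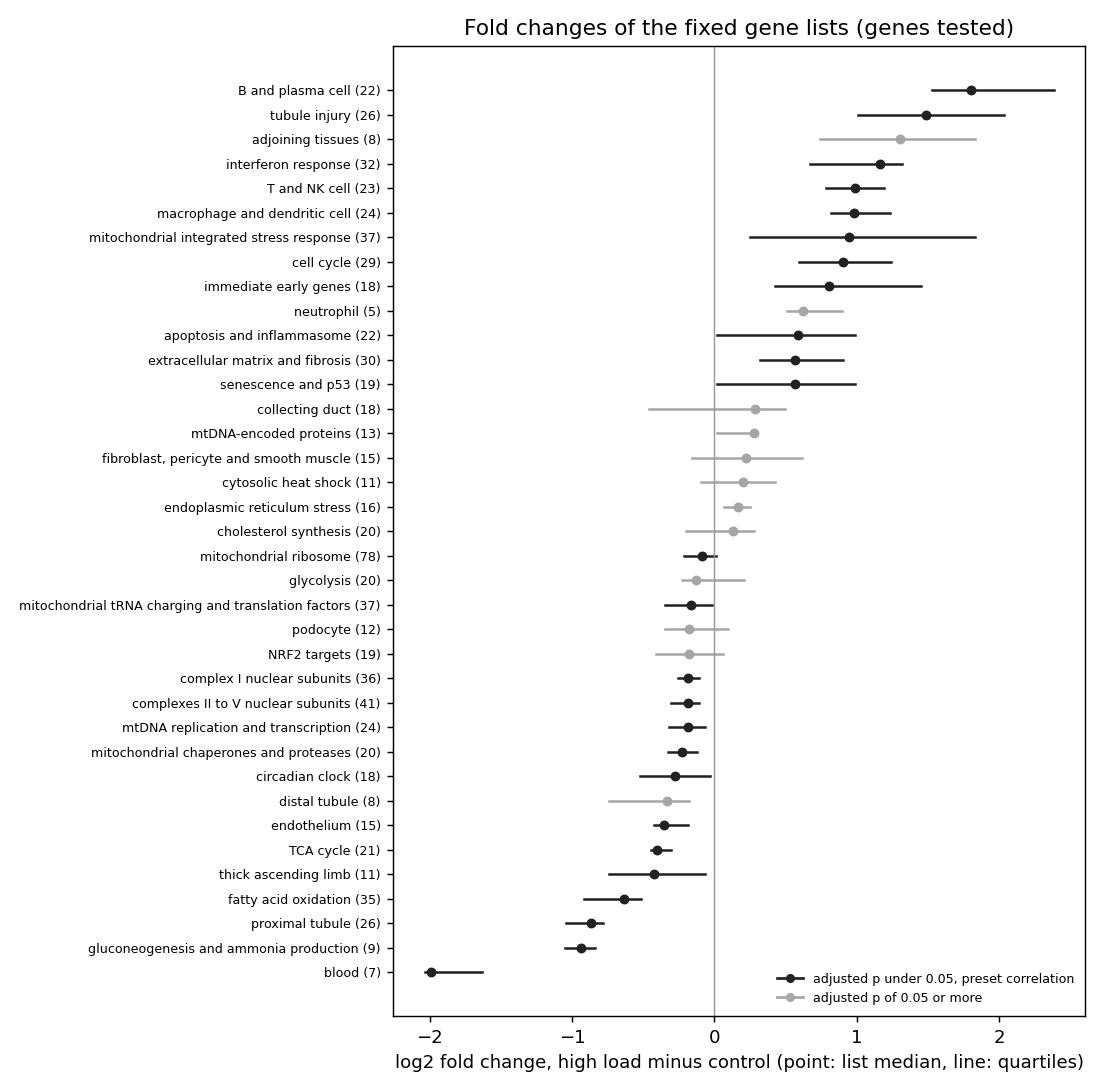
Median log2 fold change (point) and quartiles (line) of each fixed list with at least 5 tested genes, with the number tested in brackets and lists called by camera with its preset correlation in black. The stress response, interferon and tubule injury medians lie at 0.95, 1.16 and 1.48, and fatty acid oxidation and proximal tubule medians at -0.64 and -0.87.

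The remaining lists had 0 members past the threshold over all genes. Circadian clock genes were called lower (median -0.28 over 18 genes, camera adjusted p 0.0220, and adjusted p = 0.392 with an estimated correlation). Over that list alone Bhlhe41 was higher and Tef lower. The counts were 0 without any 1 of the controls or high-load 3, and 5 and 4 were lower without high-load 1 and high-load 2. The call was lost without control 1 (median -0.15, 0.0688) or high-load 3 (0.0739). Clock genes move with the hour of collection, and whether that hour differed between the groups was not tested. Glycolysis genes were not called (median -0.13, mean 0.13, camera pointing down, adjusted p 0.908), with hexokinase 2, Hk2, alone passing over the list alone (1.599 ± 0.250 and 12.2 ± 8.66 CPM), 0 without any 1 of the controls and 2 without high-load 2. The high-load mean of Hk2 was 7.33 CPM without high-load 1. The glycolysis median was -0.053 without high-load 1, -0.071 without high-load 2 and -0.20 without high-load 3, and camera pointed up without control 2 (adjusted p 0.918) or high-load 2 (adjusted p 0.509). NRF2 targets were not called (median -0.18, mean 0.08, camera pointing down, adjusted p 0.219), except lower without high-load 1 (0.0408). Their median was -0.061 without control 2, -0.098 without control 3 and -0.12 without high-load 3. Over that list alone Slc7a11 was higher and Osgin1 lower, 2 and 3 without high-load 2, and 0 without any other 1 library. Cholesterol synthesis genes were not called (median 0.13, camera adjusted p 0.398), except higher without high-load 2 (median 0.25, 0.0395), with Fdps alone passing over the list alone (19.2 ± 2.64 and 82.8 ± 32.4 CPM), and 0 without control 1. The cholesterol synthesis median was -0.012 without control 1, where camera pointed down (adjusted p 0.668), and -0.072 without high-load 1. Endoplasmic reticulum stress genes were not called (median 0.16, camera adjusted p 0.201, 0 over the list alone), except higher without control 1 (0.0326), and over the list alone 1 gene was higher without control 1 and 1 lower without high-load 2. Their median was 0.11 without control 2. Cytosolic heat shock genes were not called (median 0.20, camera adjusted p 0.117), with Hspb8 alone passing over the list alone (9.31 ± 0.948 and 25.1 ± 5.66 CPM), or 2 genes without high-load 2. Their median was 0.12 without high-load 1.

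Camera with its preset correlation called 25 of 37 lists, 11 higher and 14 lower, and with a correlation estimated from these libraries it called 0. Other groupings of the same 6 libraries into 3 and 3 gave 14 to 25 calls with the preset correlation. All 3 high-load values lay above all 3 controls for 2733 genes and below for 2527. Together these are 33.0% of genes tested, where 10% is the mean expected by chance for 3 against 3. Genes that move together can take the share far from 10% by chance. The share was not computed for other groupings, so its spread is not known.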

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

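Tests of the proximal tubule share, blood, pelvis and fat, and the rule that picked out the counts of Adipoq and Plin1, were chosen only after the results were seen. The tests of length and GC content and of scaling were set before theirs. The bound of the blood test was made stricter 2 times after its values were seen.

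Adipoq and Plin1, fat cell genes, reached the filter's minimum count in too few libraries to be tested. Their highest high-load counts were 237 and 121, at least 50 and at least 3 times the highest control. Adipoq counts were 1, 0 and 10 in controls 1 to 3 and 237, 66 and 2 in high-load 1 to 3. Plin1 counts were 0, 0 and 5 in the controls and 121, 52 and 0 in the high-load libraries.

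The first pattern is the lower expression of proximal tubule, fatty acid oxidation, TCA cycle and gluconeogenesis genes, 90 genes with a median log2 fold change of -0.64. A bias of transcript length or GC content is argued against, since the median was -0.63 (bootstrap SE 0.059) after a fit on both, which explained 0.809% of the variance, and so are scaling and mitochondrially encoded reads, since it was -0.54 with library totals alone and -0.64 without those genes. A lower share of proximal tubule cells and nothing else would raise all other cell types alike, but the macrophage score minus the endothelium score was 1.30 log2 higher in high-load kidneys (SD 0.689, against 0.149 in controls). A lower share of these cells together with more macrophages, and lower expression within tubule cells at a high mutation load, both stay open as hypotheses. Neither was tested, since bulk RNA gives no values per cell.

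The second pattern is the higher expression of macrophage, interferon, T and B cell genes. Groups overlapped for T cells, with a T and NK score of 0.22 in high-load 3 and 0.59 in control 1. More blood stays open: the red cell score averaged -1.31 in high-load kidneys (SD 0.856; -0.42, -1.40 and -2.12 in high-load 1 to 3), but control scores were -1.15, 2.06 and -0.91, the difference without control 2 was -0.28, within the SD, and high-load 1, with the highest macrophage score, lay above controls 1 and 3. Pelvis wall as the source in all 3 is argued against, since 2 high-load libraries had uroplakin scores below all controls while their macrophage scores were 0.65 and 0.81, but high-load 1, with the highest macrophage and interferon scores, had a uroplakin score of 3.06, so that pelvis tissue may add to its immune genes. Fat or a lymph node cannot be told apart from immune cells of the kidney itself, since 1 high-load library had Adipoq counts at or below the highest control and the other 2 did not. A response of the kidney to the mutation load stays open and untested.

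Other groupings of the same libraries bear on the counts. The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3 genes and the highest of the others 0 (1 split as large, the real one), 1 list member against 0 (1 split as large), and 25 lists against 25 (2 splits as large). Each of the other splits called 14 to 25 lists with the preset correlation. The number of lists called therefore does not set the real grouping apart. Each side of another split still holds 2 libraries of 1 real group, so part of a group difference can stay in its calls. Genes at an unadjusted p under 0.05 in edgeR's test numbered 3861 in the real split and 141 to 1263 in the others.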

How the results depend on the processing

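The 3 called genes stayed called with DESeq2's size factors, library totals, mitochondrially encoded genes left out, the stricter filter, no robust estimation, and a fold of at least 2. Other settings moved the number of genes called (higher and lower in brackets) from 3 (3 and 0): 50 (46 and 4) with no filter on low counts, 10 (8 and 2) with mutation load as a number, 511 (414 and 97) at an adjusted p under 0.1, 1698 (1074 and 624) with DESeq2 and its own filtering, and 0 with limma-voom, which had 3788 genes at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 807 genes (0 to 544 higher, 0 to 263 lower). Members of the fixed lists called, 1 in all, became 15, 4, 80, 208 and 0 under the same 5 settings, and 0 to 105 with 1 library left out. DESeq2 on the genes of the main test, added after seeing the data, called 1711 (1069 and 642; 212 members), so that the other set of genes is not why it called more. In the simulation, on 15955 genes, it made 63 false calls against 10. Why leaving out high-load 2 raised the count was not tested.

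Adjusted p over all settings ran from 1.09e-33 (DESeq2) to 0.259 (without control 2) for Atf5, from 3.93e-52 to 0.260 for S100a14 and from 6.27e-18 to 0.260 for Kcnk3, with log2 fold changes from 2.44 to 2.71, 5.89 to 6.52 and 3.05 to 3.40. The median log2 fold change of all genes was 0.126 with library totals and 0.00675 with TMM.

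The replicate block left 1 gene called, Atf5, and 25 lists. The numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.12, -0.18 and 0.05.

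Of 25 lists called, an estimated correlation kept 0 and fry called 2, of which 1 was among the 25. Library totals kept 24 and the added DESeq2 size factors 25. Leaving out 1 library gave 23 to 26 called lists, of which 21 to 25 were among the 25. The number kept was 21 without control 2 or high-load 1. The adjoining tissue list, down with all libraries and without high-load 1, turned up without any 1 of the other 5, with a call without high-load 3 (adjusted p 0.00393, over a range of 5.57e-09 to 0.946 with each library left out). The cause was not tested. Total counts of 17449270 to 18865997 overlap between groups, and the biological coefficient of variation was 22.97%. Pairs of libraries within a group differed by 21.4 to 100.02 times the variance of counting noise. Averaged over genes, spread between libraries therefore exceeded counting noise. How the calls would change with depth was not tested.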

Other observations

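The 7 lists and tests here were chosen only after the genes with the smallest p-values had been seen, and members seen by then were left out of the V-ATPase, tRNA synthetase and complement lists. Camera p-values are adjusted over these 7 lists and do not allow for this choice.

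Genes that present antigen on MHC class I were higher in high-load kidneys, with 13 of 13 above a fold change of 1 and a median log2 fold change of 0.64 (camera adjusted p 2.10e-07, and adjusted p = 0.261 with an estimated correlation). B2m, the light chain of MHC class I, was at 476 ± 48.7 CPM in controls and 853 ± 153 CPM in high-load kidneys, H2-K1 at 447 ± 69.9 and 999.6 ± 399 CPM, and the transactivator Nlrc5 at 15.7 ± 4.91 and 45.5 ± 22.1 CPM. Adjusted over the list alone 11 passed, or 5 without control 2, and 0 passed over all genes. Reads of the H2 genes can be shared between near-identical copies. Complement genes had a median of 0.37 over 13 genes (camera adjusted p 0.00574, and adjusted p = 0.212 with an estimated correlation), with C3ar1, a receptor of macrophages, at 8.01 ± 0.635 and 19.2 ± 6.52 CPM and complement factor B, Cfb, at 359.8 ± 42.1 and 237 ± 49.7 CPM. Over that list alone 2 passed, 0 without control 1 or control 3, 1 without high-load 1, and 5 without high-load 2 or high-load 3, and the median was 0.23 without high-load 2.

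Organic ion transporters, which carry drugs and urate across the tubule wall, were lower, with 0 of 17 above a fold change of 1 and a median of -0.80 (camera adjusted p 2.85e-07, and adjusted p = 0.261 with an estimated correlation). The urate carrier Slc22a12 was at 713 ± 162 and 387 ± 115 CPM and Slc47a1 at 594 ± 110.0 and 321 ± 111 CPM, and 0 passed over the list alone, or 10 without high-load 2. The median was -0.53 without high-load 1. Proximal tubule markers had a median of -0.87, or -0.57 without high-load 1. Whether the transporters fell apart from those markers was not tested. Cytosolic ribosomal protein genes were higher by a small amount, with 55 of 56 above a fold change of 1 and a median of 0.25 (camera adjusted p 2.24e-05, and adjusted p = 0.594 with an estimated correlation). None passed over the list alone, or 1 without high-load 1, where the median was 0.13 and the camera adjusted p 0.00430.

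The hypotheses tested number 2. The first was that the higher proton pump subunits seen among the leading genes belong to a general rise of lysosomal acidification genes. The V-ATPase list without those subunits had a median of -0.06 over 19 genes and a camera adjusted p of 0.589, pointing down, and 1 gene passed over the list alone without high-load 2. The median was -0.041 without control 2, -0.12 without high-load 3 and 0.015 without high-load 1, where camera pointed up (adjusted p 0.495). No such rise was found with all libraries or with any 1 left out. The lysosome list was called higher (median 0.11 over 28 genes, camera adjusted p 0.0300, and adjusted p = 0.212 with an estimated correlation), with 6 members past the list's own adjustment, such as Grn and Gpnmb (3.49 ± 2.61 and 39.4 ± 24.7 CPM, with means of 2.01 without control 1 and 25.5 without high-load 1). That call was lost without control 1 (0.0722), high-load 2 (0.0515) or high-load 3 (0.0864), and the 6 became 2 without control 1 and 0 without control 2, control 3 or high-load 3. Macrophage and dendritic cell markers were higher too (median 0.98), and whether lysosome genes rose apart from them was not tested. The second was that cytosolic tRNA synthetases rise with the stress response. The 15 genes tested had a median of 0.17 and a camera adjusted p of 0.194, and were called only without control 2 (0.0397). The median was 0.055 without high-load 1. None passed over the list alone, or 2 without high-load 2.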
